A study of Nothobranchius furzeri with 15 samples.

How the data were processed

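RNA-seq gene counts of skin from the turquoise killifish (Nothobranchius furzeri), a short-lived annual fish, were analysed. All 15 samples came from males of the GRZ strain, a highly inbred laboratory strain, at 9 weeks of age per the labels. They fell into 3 groups of 5 samples each: fish given the solvent dimethyl sulfoxide (DMSO), 15 pM rotenone or 150 pM rotenone. Rotenone is an inhibitor of respiratory complex I of the mitochondria. Groups were taken from the labels, and the replicates of a group are numbered 1 to 5 in the order in which the samples were registered. The labels list separate samples but do not say in so many words that each came from another fish, so p-values measure the spread between these samples, which may be partly technical.

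Libraries were made from total RNA with the TruSeq RNA version 2 kit per the labels' protocols, a kit that does not mark the strand, so reads of a gene and an overlapping antisense gene cannot be told apart. Base calling with CASAVA 1.8.2, alignment with STAR 2.4.1d and read counting with featureCounts 1.4.6-p4 are named in the submitters' processing notes. The genome build, the gene annotation and the counting options are not given in the sources used here. The authors deposited 2 tables with the same 26739 gene rows, a table of raw counts and a table of RPKM values (read counts divided by gene length and by a library total). Whether reads shared by near-identical gene copies were dropped or assigned is not given in the sources used here, so the counts of such genes are uncertain.

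The deposited RPKM values were checked against the deposited counts. For 3936 genes with over 500 counts and an RPKM over 0.5 in every sample, the gene length that follows from count, RPKM and the sample's own total count was the same in all 15 samples, within 1%, for 0% of the genes. When the 15 totals were instead repeated down the rows of the table, so that neighbouring rows of 1 sample were divided by totals of different samples, 100% of the genes had 1 length. The deposited RPKM therefore differ from RPKM computed with the sample's own total by factors of 0.772 to 1.30, depending on the row and the sample. Each sample's values were thus divided by a mix of all 15 totals, so the deposited RPKM are not corrected for the sample's own depth. The counts were used for every reported result, and the RPKM only for an alternative and for gene lengths.

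Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 18253 genes, and libraries were scaled by TMM factors. All 15 samples entered 1 fit with a mean per group and no covariates, so the 3 groups shared each gene's estimate of the spread. The 3 pairwise comparisons used edgeR's quasi-likelihood test, and a test over both rotenone doses used the same fit. P-values were adjusted by the Benjamini-Hochberg method within a comparison, and a gene was called changed at an adjusted p under 0.05. Levels are given as CPM, a gene's count scaled to a common library total, with TMM factors. Single values per sample were compared by exact two-sided permutation tests over the 252 arrangements of 5 against 5 samples, whose smallest p is 0.00794. The steps were tested on simulated data with 200 changed genes among 18253: for 15 pM rotenone against DMSO, 72% of the genes changed by 2 on the log2 scale and 37% of those changed by 1 were recovered, for 150 pM against DMSO 82% and 25%, and for 150 pM against 15 pM 72% and 40%, with 2.68%, 2.73% and 4.27% false calls. These simulations drew each gene independently, with the same spread in all groups and no outlying sample. The rates may therefore not hold for the real samples.

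The files identify genes by numbered identifiers and do not pair them with names. The table of RefSeq gene names used here holds 38438 genes and matched 0 of the 26739 identifiers, so no gene is named. For this reason the 39 lists of pathways, complexes and cell types, the level of the complex I subunits and the rule for choosing named genes, all of which need names and were fixed before the data were examined, were not used. In their place the gene with the smallest p among the raised and among the lowered genes of each dose against DMSO is given by its identifier, a choice made after the values were seen. Skin composition by cell type was not analysed here for the same reason.

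The samples, the tests, their design and most alternatives were fixed before the data were examined. The alternatives were DESeq2 size factors or upper-quartile factors in edgeR, no filter on low counts, a filter of at least 1 CPM in 5 samples, a fit of only the 2 groups compared, the DESeq2 1.42.0 Wald test, limma 3.58.1 with voom and sample quality weights, limma-trend on log2(RPKM + 0.1), the title numbers of the samples as blocks, and leaving out each sample of the compared groups. Leaving out a sample of the group not compared, leaving out the 20 most abundant genes, and RPKM computed with each sample's own total were added after the data were seen.

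The total count per sample was 21857670 to 28314659. Within groups, all 30 pairs of samples differed by more than sampling noise, with a chi-square statistic of at least 24.2 times its degrees of freedom, so that no pair appeared to be copies of 1 library. This does not show that the samples came from separate fish.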

Results

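Gene expression in the skin of 9-week-old male killifish was measured by RNA-seq after exposure to the complex I inhibitor rotenone at 15 pM or 150 pM, with fish given the solvent DMSO as controls. Each of the 3 groups held 5 samples. The total count per sample had a median of 24600127 and ranged from 21857670 to 28314659. It averaged 25978514 ± 1577773 counts (SD, n = 5) in the DMSO group, 23869222 ± 1769273 in the 15 pM group and 25180299 ± 1788767 in the 150 pM group. The exact permutation tests found no difference in total count past the threshold, with the smallest p of 0.0952 for 15 pM against DMSO and an adjusted p of 0.602 over 9 tests of sample properties. Between 20723 and 21505 genes had at least 1 count in a sample. At this depth, 18253 genes entered the tests.

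The most abundant genes took a varying share of the counts. The 20 most abundant genes of a sample held 29.6 ± 3.15% of its counts in the DMSO group, 24.9 ± 7.48% in the 15 pM group and 27.9 ± 2.80% in the 150 pM group (SD, n = 5). In the 15 pM group, replicate 4 had 15.9% and replicate 1 had 18.1%, whereas the other samples of the series had 24.8% to 33.4%. The expression profile of 15 pM replicate 4 also lay farthest from the rest of its group, at a root mean square distance of 1.08 in log2 CPM. The distances of the other samples were 0.425 to 0.890. The mean correlation of log2 CPM across genes was 0.931 within and 0.927 between the 15 pM and DMSO groups. In 31 of the 126 ways to split these 10 samples into 5 and 5 the difference was as large (exact one-sided p = 0.246, adjusted p = 0.246 over the 3 comparisons). For 150 pM against DMSO the correlations were 0.948 within and 0.943 between groups (exact p = 0.135, adjusted p = 0.202). For 150 pM against 15 pM they were 0.939 within and 0.929 between groups (exact p = 0.0159, adjusted p = 0.0476).

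**Figure D1:**
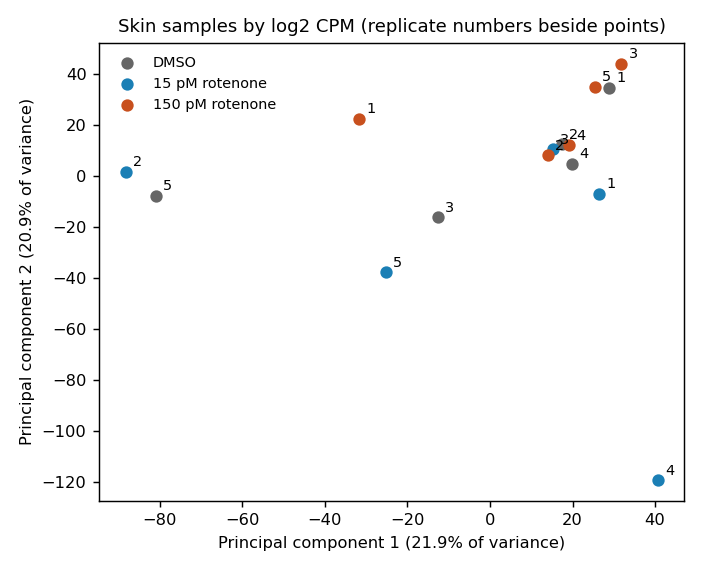
The first 2 principal components of log2 CPM are plotted for the 15 skin samples, which are coloured by group and carry their replicate number. The components hold 21.9% and 20.9% of the variance, and 15 pM replicate 4 lies apart from the other 14 samples on the second. On the first, 15 pM replicate 2 and DMSO replicate 5 lie apart at -88.2 and -80.9, so this component does not follow the groups. All other samples lie between -31.7 and 40.7 on it.

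The lower dose was compared with the solvent to ask which genes changed at 15 pM rotenone. The gene with the smallest p was Nfu_g_1_007507, which was close to background in DMSO skin and rose at 15 pM in every sample. It had 2.15 ± 1.39 CPM in the DMSO group and 219.7 ± 59.7 CPM in the 15 pM group (SD, n = 5), from 33 to 109 counts per DMSO sample and 3467 to 7133 counts per 15 pM sample. Its log2 fold change was 6.68 with a standard error of 0.41, and its adjusted p by edgeR's quasi-likelihood test was 1.33e-06. Among the lowered genes, Nfu_g_1_010543 had the smallest p. Its level fell from 91.5 ± 11.7 CPM in DMSO skin to 39.1 ± 4.80 CPM at 15 pM (SD, n = 5), with a log2 fold change of -1.23, a standard error of 0.14 and an adjusted p of 0.00115 by the same test. This call was lost in 1 of 26 alternatives, the fit of only these 2 groups with the title numbers as blocks, and the adjusted p over all alternatives was 2.69e-13 to 0.134.

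In all, 320 of the 18253 tested genes were called changed at 15 pM, 196 of them raised and 124 lowered. The raised genes had a median log2 fold change of 0.93 and the lowered ones of -0.91. Changes of over 1 on the log2 scale were seen for 84 raised and 47 lowered genes. The largest changes were nearly all increases, with 18 raised genes and 4 lowered genes over 2 and with 9 raised genes and 0 lowered genes over 4. Among the called genes, 279 had no overlap between the 5 samples of 1 group and the 5 of the other. Over all tested genes this held for 6.15%, where the average over all splits of the samples is 0.794%. Genes vary together between samples, so a single split can lie far from that average, and other splits were not examined for it. At an unadjusted p under 0.05 there were 3906 genes. The same fit without the filter or with other scaling factors stayed within 1.5 times this count, but the count differed widely between tests and sets of samples. It was 86 when only these 10 samples were fitted and 2 when that fit also took the title numbers as blocks. By the DESeq2 Wald test it was 1513, and by limma-voom with sample quality weights 1930. Without 15 pM replicate 4 it was 798, without 15 pM replicate 2 it was 652, and without 15 pM replicate 3 it was 191. Leaving out DMSO replicate 1, 2, 4 or 5 gave 145, 118, 119 and 180 genes, and leaving out 150 pM replicate 5 gave 209. In the fits with 1 sample left out, 57.8% to 74.1% of the called genes were raised. With scaling alone changed, 211 raised and 120 lowered genes were called with DESeq2 size factors and 183 raised and 155 lowered genes with upper-quartile factors. On log2 RPKM, where the test, the values and the scaling all differ, the balance of directions was another. Limma-trend on the deposited RPKM called 57 raised and 190 lowered genes, with a median log2 fold change of all tested genes of -0.17. The deposited values are not corrected for a sample's own total, which averaged 23869222 at 15 pM and 25978514 in DMSO. This difference in depth lowers the 15 pM values on average. On RPKM with each sample's own total 99 raised and 112 lowered genes were called, the median then being -0.05.

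The higher dose was compared with the same DMSO samples. Nfu_g_1_019963 had the smallest p and was raised. Its level was 30.4 ± 0.860 CPM in the DMSO group and 53.1 ± 6.71 CPM at 150 pM (SD, n = 5), a log2 fold change of 0.81 with a standard error of 0.10 and an adjusted p of 0.0112 by edgeR's quasi-likelihood test. It was raised at 15 pM too, to 51.6 ± 3.83 CPM (log2 fold change 0.77, adjusted p = 0.00233), and the doses differed by 0.04 on the log2 scale, less than the standard error of 0.10. Its call at 15 pM was lost in 2 of 26 alternatives, on the deposited RPKM (adjusted p = 0.0522) and in the fit of only the 2 groups with title numbers as blocks, with adjusted p from 1.88e-13 to 0.154 over all alternatives. The lowered gene with the smallest p was Nfu_g_1_013270, which fell from 52.2 ± 17.4 CPM in DMSO skin to 17.9 ± 2.19 CPM at 150 pM (SD, n = 5; log2 fold change -1.55, standard error 0.21, adjusted p = 0.0136). This gene had 31.4 ± 5.82 CPM at 15 pM, where its log2 fold change of -0.73 did not pass the threshold (adjusted p = 0.0736), although it passed in 3 of 26 alternatives, DESeq2, limma-voom and the deposited RPKM, with adjusted p from 0.0182 to 0.252 over all alternatives. The call of Nfu_g_1_019963 at 150 pM was lost on log2 RPKM, with an adjusted p of 0.136 on the deposited values and 0.0847 with own totals. The call of Nfu_g_1_013270 was lost without 150 pM replicate 5, with an adjusted p of 0.0529. Over all alternatives the adjusted p at 150 pM was 4.83e-14 to 0.136 for the former gene and 4.46e-09 to 0.0529 for the latter.

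**Figure D2:**
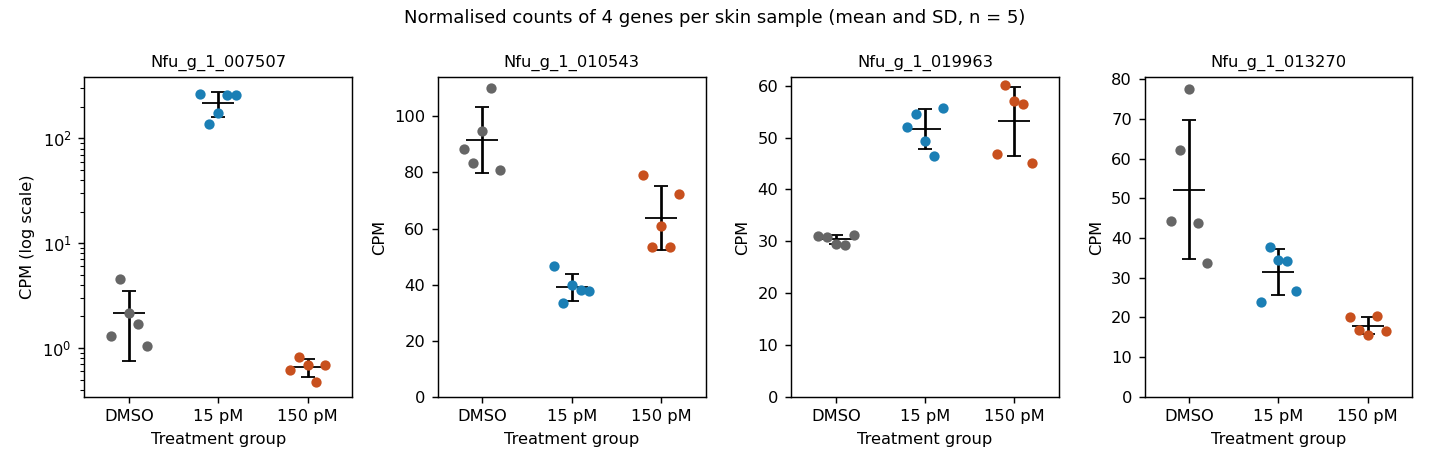
TMM-scaled CPM values are plotted for each of the 5 skin samples of the 3 groups for the 4 genes given by identifier, with the mean as a horizontal line and the SD as an error bar, and with a log axis for the first gene alone. The 15 pM samples of Nfu_g_1_007507 lie between 137 and 266 CPM, all above the highest DMSO sample at 4.52 CPM, and the 150 pM samples of Nfu_g_1_013270 lie between 15.7 and 20.4 CPM.

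At 150 pM, 19 genes were called changed in the fit of all 15 samples, 11 raised and 8 lowered. The raised genes had a median log2 fold change of 0.84 and the lowered ones of -1.21, and no change reached 2 on the log2 scale. The 5 samples of each group did not overlap in any of these 19 genes. Over all tested genes they did not overlap for 7.96%, against an average of 0.794% over all splits, from which a single split can lie far. At an unadjusted p under 0.05 there were 2764 genes. The number of calls differed widely between fits. Fitted without the 15 pM group, the comparison gave 508 genes, 279 raised and 229 lowered, and all 19 genes were among them. The DESeq2 Wald test called 657 genes, 228 raised and 429 lowered, and limma-voom with sample quality weights 2341, 1128 raised and 1213 lowered. Leaving 15 pM replicate 4 out of the fit of all groups gave 342 genes, 177 raised and 165 lowered, although that sample belongs to neither group compared. Without DMSO replicate 1 the count was 62, with 45 raised and 17 lowered genes, without DMSO replicate 2 it was 4, and without DMSO replicate 4 it was 8. Leaving out 150 pM replicate 1, 3, 4 or 5 gave 11, 7, 12 and 1 genes. On log2 RPKM limma-trend called 0 raised and 4 lowered genes with the deposited values and 0 raised and 3 lowered genes with own totals, the numbers of genes at an unadjusted p under 0.05 being 2291 and 2177.

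**Figure D3:**
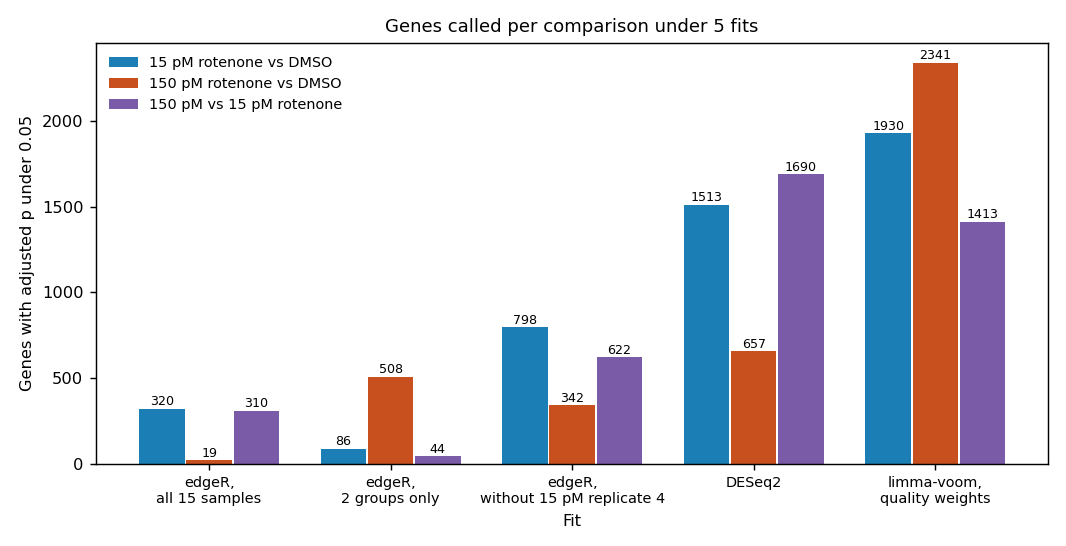
Bars give the number of genes with an adjusted p under 0.05 in each of the 3 comparisons under 5 fits. In the edgeR fit of all 15 samples the counts are 320, 19 and 310, and in fits of only the 2 groups compared they are 86, 508 and 44, so that the order of the doses is not the same.

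The doses were also compared directly. The gene with the smallest p was again Nfu_g_1_007507, which had 0.657 ± 0.125 CPM at 150 pM (SD, n = 5), from 12 to 22 counts per sample, against 219.7 CPM at 15 pM. The log2 fold change of 150 pM against 15 pM was -8.37 with a standard error of 0.44 and an adjusted p of 1.93e-07 by edgeR's quasi-likelihood test. Against DMSO its log2 fold change at 150 pM was -1.69 with an adjusted p of 0.0953, so that it was not called different from the solvent level in the fit of all samples. It was called lower in 4 of 25 alternatives, by DESeq2 (adjusted p = 0.00187), by limma-voom (0.0324), with only the 2 groups (0.0489) and without 15 pM replicate 4 (0.0443), and the adjusted p over all alternatives was 0.00187 to 0.230. Nfu_g_1_010543 was less lowered at 150 pM, with 63.8 ± 11.45 CPM (SD, n = 5), than at 15 pM. The doses differed by 0.71 on the log2 scale for this gene (standard error 0.14, adjusted p = 0.0271), and 150 pM against DMSO gave -0.52 with an adjusted p of 0.124, which passed the threshold in 2 of 25 alternatives, DESeq2 and limma-voom (adjusted p from 0.0185 to 0.300 over all alternatives). The call between doses was lost in 8 of 25 alternatives, among them the fits without 15 pM replicate 2 or 3 and without 150 pM replicate 1, 3 or 5, with adjusted p from 0.000393 to 0.0987 over all alternatives. Nfu_g_1_013270 was 0.81 lower at 150 pM on the log2 scale, with an adjusted p of 0.0542. This difference passed the threshold in 6 of 25 alternatives, namely with the CPM filter, DESeq2 or limma-voom and without DMSO replicate 3, DMSO replicate 5 or 15 pM replicate 1, with adjusted p from 0.00650 to 0.134 over all alternatives.

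Between the doses 310 genes were called, 146 higher and 164 lower at 150 pM. The median log2 fold change was 0.91 for the former and -0.81 for the latter. Of these genes, 91 were also called at 15 pM against DMSO, and 215 were called in neither comparison with DMSO. The largest differences were genes that were high at 15 pM: 17 genes were lower at 150 pM by over 2 on the log2 scale, 8 of them by over 4, against 8 and 1 genes that were higher by as much. The 8 genes with the largest decrease were also raised at 15 pM against DMSO, with log2 fold changes of 4.02 to 7.82 and adjusted p from 1.33e-06 to 0.0108. Both comparisons used the same 15 pM samples, so calls shared between them are not independent. Choosing these genes by their decrease also favours a gap to the 150 pM samples. For 7 of these 8 genes each 15 pM sample lay above every DMSO and 150 pM sample. Of the 310 genes, 268 had no overlap between the samples of the doses. Over all tested genes this held for 5.41%, against an average of 0.794% over all splits, from which a single split can lie far. The count was 199 without a filter on low counts, 44 when only these 10 samples were fitted, 1690 by DESeq2 and 1413 by limma-voom with quality weights. It was 58 on the deposited RPKM and 73 on RPKM with own totals, the latter with 21 genes higher and 52 lower at 150 pM. Leaving out 15 pM replicate 1, 2, 3, 4 or 5 gave 501, 187, 55, 622 and 184 genes. Leaving out 150 pM replicate 1, 2, 3 or 5 gave 72, 144, 50 and 35 genes, and leaving out DMSO replicate 2, 4 or 5 gave 153, 110 and 203. The near-even balance of directions was not kept throughout. There were 70 genes higher and 129 lower at 150 pM without a filter, 42 and 145 without 15 pM replicate 2, 11 and 44 without 15 pM replicate 3, 16 and 56 without 150 pM replicate 1, 10 and 40 without 150 pM replicate 3, 8 and 27 without 150 pM replicate 5, and 31 and 79 without DMSO replicate 4. Over all fits with 1 sample left out, 20% to 56.4% of the called genes were higher at 150 pM.

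Over the 3 groups together, 425 genes differed by edgeR's test of both rotenone coefficients, 2.33% of those tested. This count was 4385 by limma-voom with quality weights. It was 1263 without 15 pM replicate 4 and 149 without 15 pM replicate 3. Leaving out DMSO replicate 2, 4 or 5 gave 125, 111 and 189 genes, and leaving out 150 pM replicate 1, 2, 3 or 5 gave 220, 257, 180 and 142.

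Whether the doses moved the same genes was examined from the fold changes against DMSO. Of the 320 genes called at 15 pM, 277 had the same sign at 150 pM, with a median log2 fold change at 150 pM of 0.30 for the raised genes and of -0.30 for the lowered ones. All 19 genes called at 150 pM had the same sign at 15 pM. Calls in both comparisons were made for 3 genes, 2 raised and 1 lowered, where independent lists of these sizes would share 0.118 and 0.0543 genes. Both comparisons used the same 5 DMSO samples, however. In 50 simulations of 3 unchanged groups, 0.26 genes on average and at most 3 were called in both. The simulated lists held 1.18 genes on average at 15 pM and 0.4 at 150 pM. Their overlap is therefore no measure for lists of 320 and 19 genes. In these simulations the 300 genes with the smallest p at 15 pM had the same sign at 150 pM in 86.1 ± 2.31% of cases (SD over simulations), against 86.7% in the data. Across the 18253 genes, which are not independent replicates, the correlation of the log2 fold changes was r = 0.36 and rho = 0.36. The simulations gave r = 0.51, from 0.49 to 0.55, and rho = 0.41. The covariance was 0.104, against 0.0804 ± 0.00435 in the simulations. When the DMSO samples were split so that the doses had 2 and 3 controls of their own, the median over the 20 assignments was r = -0.17, from -0.40 to 0.13, and rho = 0.14, from -0.04 to 0.26. The 300 genes with the smallest p at 15 pM then had the same sign at 150 pM in a median of 70.3% of cases, from 58.3% to 82.3%. The measures thus differed. With shared controls r and rho lay below all simulations, rho below a lowest simulated value of 0.399. So did the same-sign share over all genes, at 62.7% against at least 63.1%. The same-sign share of the 300 genes lay within the simulated spread, and the covariance lay above the highest simulated value of 0.0901. With separate controls the median r was negative and the median rho positive. The simulations drew each gene independently, without the joint variation of genes between samples. Their spread may therefore be too narrow, and a value outside it decides nothing about shared effects.

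**Figure D4:**
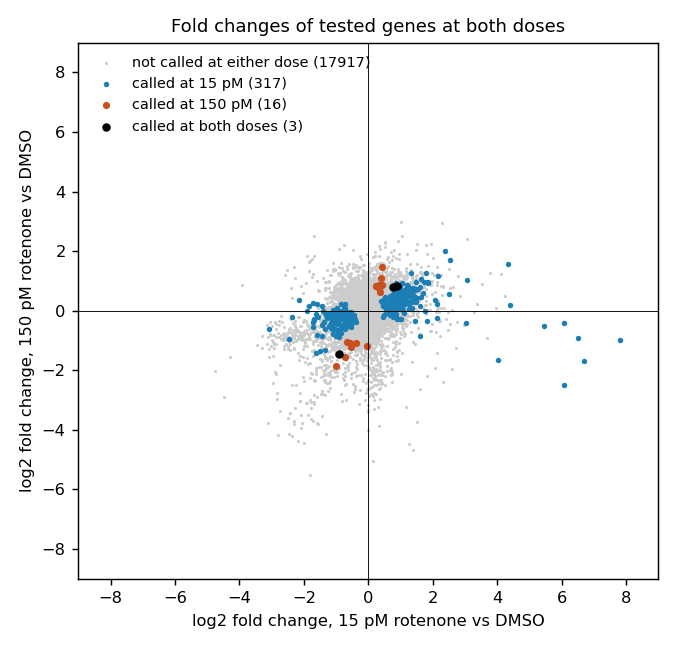
The log2 fold change against DMSO is plotted for 18253 tested genes at 15 pM (horizontal) and at 150 pM (vertical), coloured by the comparison in which a gene was called. Of the 9 genes raised by over 4 at 15 pM, 7 lie below 0 at 150 pM, and 3 genes were called at both doses.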

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

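The tests of neighbouring genes, of single libraries, of 15 pM replicate 4 and of exchanged labels were chosen after the values were seen. The test without the most abundant genes and the counts over other splits of the samples were set before their results were seen.

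A sample far from the rest of its group was found in 2 of 24 groups of 5 values examined, and chance gives about 1 in 20. The 150 pM replicate 2 had a total count of 28314659, against 23983152 to 24878602 in the other 150 pM samples. In DMSO replicate 5, 21505 genes had at least 1 count, against 20966 to 21085 in the other DMSO samples. Outside its group, 150 pM replicate 1 had 21402 such genes and 15 pM replicate 2 had 21311. On the first principal component these samples stood at -31.7 and -88.2, and DMSO replicate 5 at -80.9.

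The effects of the doses differed by the direct test of 150 pM against 15 pM for 310 genes. Among the genes given by identifier, the log2 difference was -8.37 for Nfu_g_1_007507 and 0.71 for Nfu_g_1_010543. The 310 genes were matched or exceeded by 1 of 100 splits of these 10 samples, the real one, with at most 5 genes in any other. For 15 pM against DMSO the real split gave 320 genes and the other splits at most 1, so that 1 of 100 splits gave as many. Over the 3 groups the real grouping gave 425 genes and the highest of the others 132, again with 1 of 100 as large. For each of these 3 counts, under 5% of the splits thus gave as many genes. Such splits take the samples as independent, which the labels do not show. They cannot exclude a difference that coincides with the groups for a reason other than the dose.

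Nfu_g_1_007507 belongs to a set of 8 genes that were raised at 15 pM, with means of at most 10.3 CPM in DMSO and 3.28 CPM at 150 pM, and 5 of the 8 stand within 9 rows of the deposited table while 2 others stand in adjacent rows. A single library as the source is argued against: when each 15 pM sample in turn was left out of the choice of such genes, 7 or 8 genes were chosen, and in all 5 of these samples at least 7 of them lay above every DMSO and 150 pM sample. Most of the 110 tested genes within 25 rows did not share so large a change. Their median log2 fold change at 15 pM against DMSO was 0.09. Between the doses 3 of them were called, where 1.70% of all tested genes were called. A weaker linked difference over a wide stretch of the table stays open, because 40% of simulated changes of 1 on the log2 scale were recovered. More cells of a kind that also makes the 2 abundant genes in the next rows stays open: the summed level of these neighbours was 971 CPM higher at 15 pM than in DMSO (exact two-sided p = 0.0397), although DMSO replicate 2 had 2129 CPM, above the 15 pM mean of 1815 CPM, and neither neighbour alone passed the threshold of edgeR's test. A local response to the lower dose and cells that make these genes alone stay open too, and the sources used here do not say whether table rows follow the genome.

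The comparison of 150 pM with DMSO called 19 genes in the fit of all samples, and 2 of 100 splits gave as many. That share does not exclude chance, because the highest of the other splits gave 137 genes, several times the real count. This other split exchanged DMSO replicate 1 and 150 pM replicate 2, and its count points to a structure of the samples. Genes called without both samples, 144 raised and 16 lowered, gave a divided answer on exchanged labels. On the 15 lowered genes that were also tested in the fit of all samples 150 pM replicate 2 lay at 0.905 of the way from DMSO to 150 pM and DMSO replicate 1 at 0.222, which argues against a full exchange of the samples. On the 144 raised genes DMSO replicate 1 lay at 0.910, as an exchange would give, and 150 pM replicate 2 at 0.412, between the groups, and what set these genes apart in both samples stays open. Without the 20 most abundant genes the count was 19, and the log2 fold changes moved by at most 0.00121. By the rule set beforehand, a count within 1.5 times argues against their share as the cause of the low count. With TMM scaling, the counts of these genes thus barely entered this comparison. Because the fold changes hardly moved, the test does not tell whether other differences between samples go with that share. The low count may come from the spread of 15 pM replicate 4, without which the same comparison gave 342 genes. Leaving out another 15 pM sample gave at most 24. In fits of only the 2 groups compared, the counts with 15 pM instead fell, from 320 to 86 against DMSO and from 310 to 44 between doses. Distances from the rest of the group were 0.582 to 1.08 at 15 pM and 0.425 to 0.731 at 150 pM. A shared spread may thus lower the count at 150 pM and raise the others, but fits of 2 groups also hold fewer samples. The counts therefore do not rank the doses, and no biological explanation of the low count was tested.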

How the results depend on the processing

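The fits that left out a sample of the group not compared, the 20 most abundant genes, RPKM with own totals, every refit of the 3-group count with a sample left out, and the settings for the agreement of doses other than split controls, the CPM filter and DESeq2 factors were added after the data were seen; the cause of the changes below was not tested except where stated for 15 pM replicate 4. For 15 pM against DMSO the 320 genes became 1513 with DESeq2, 1930 with limma-voom and quality weights, 86 with only the 2 groups and 211 on RPKM with own totals, and leaving out 1 sample gave 118 to 798. For 150 pM against DMSO the 19 genes became 657 with DESeq2, 2341 with limma-voom, 508 with only the 2 groups, 4 on the deposited RPKM and 3 on RPKM with own totals, and leaving out 1 sample gave 1 to 342. For 150 pM against 15 pM the 310 genes became 199 without a filter, 1690 with DESeq2, 1413 with limma-voom, 44 with only the 2 groups, 58 on the deposited RPKM and 73 with own totals, and leaving out 1 sample gave 35 to 622. The 425 genes differing among 3 groups became 4385 with limma-voom, and leaving out 1 sample gave 111 to 1263. The other scaling factors and filters kept these counts within 1.5 times. The correlation of the doses' fold changes, 0.36, reversed to -0.17 with split controls, where the rank correlation stayed positive at a median of 0.14, and was 0.42 without a filter, 0.33 with the CPM filter, 0.44 with limma-voom, 0.31 on the deposited RPKM, 0.31 on RPKM with own totals, and 0.27 to 0.51 when leaving out 1 sample. The title numbers 1 to 5 shared by the DMSO and 15 pM samples gave no clear sign of pairing. Same-numbered samples deviated together with r over 0.1 in 2 of 5 pairs, from -0.26 to 0.34. Of 5 DMSO samples, 0 correlated best with their own number. The labels do not say what these numbers mark, and 5 pairs are too few to exclude a pairing. The 150 pM samples carried title numbers 8 to 12, so an order or batch behind the numbers could not be told apart from the dose. With the numbers 1 to 5 as a replicate block in the fit of only the DMSO and 15 pM groups the count for 15 pM was 2, against 86 in that fit without the block. No fold change past its threshold turned its direction for the 4 genes given by identifier under any alternative run. The tests of gene lists and of complex I subunits were not run, since the identifiers have no names. Depth limits the genes near background: Nfu_g_1_007507 had 12 to 22 counts per 150 pM sample.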

Other observations

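The tests and values in this part were chosen after the data were seen.

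The 8 genes that were high at 15 pM differed widely in level. Their mean at 15 pM ran from 5.63 to 219.7 CPM, their mean in DMSO from 0.26 to 10.3 CPM and their mean at 150 pM from 0.04 to 3.28 CPM. Gene lengths that follow from the deposited RPKM ran from 432 to 1416 bases, and the 4 shortest genes lay between 432 and 444 bases. The sequences were not compared here, so reads shared between near-identical copies among them remain uncertain. The 2 abundant genes in the next rows had 546 and 298 CPM in DMSO skin, 1260 and 555 CPM at 15 pM and 510 and 228 CPM at 150 pM on average. Their log2 fold changes at 15 pM of 1.21 and 0.90 did not pass the threshold by edgeR's quasi-likelihood test (adjusted p = 0.113 and 0.235). DMSO replicate 2 had 1356 and 773 CPM of these neighbours and 4.52 CPM of Nfu_g_1_007507.

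A group of genes raised at 150 pM was also high in DMSO replicate 1. When DMSO replicate 1 and 150 pM replicate 2 were both left out, edgeR called 160 genes between 150 pM and DMSO, 144 raised and 16 lowered. On the 144 raised genes, with 0 at the DMSO level and 1 at the 150 pM level, DMSO replicate 1 had a median position of 0.910 and the other DMSO samples -0.133 to 0.0816. The 150 pM replicate 2 stood at 0.412, against 0.746 to 1.14 for the other 150 pM samples. The other samples of both groups took part in the choice of these genes, which draws them towards 0 and 1. DMSO replicate 1 and 150 pM replicate 2 took no part in it, so the positions are not fully comparable. On 15 lowered genes that were also tested in the fit of all samples, DMSO replicate 1 stood at 0.222, within the -0.486 to 0.243 of the other DMSO samples.

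The deposited RPKM values imply different lengths of 1 gene in different samples if each value is divided by its own sample's total. Of 3936 well-covered genes, 100% had 1 length in all 15 samples, within 1%, when the totals were repeated down the rows of the table, and 0% with own totals. For these genes, the values argue against division by each sample's own total. They match a division in which most values were divided by the total of another sample. How this arose was not tested.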
